A study of Tursiops truncatus with 116 samples.

How the data were processed

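The data are skin RNA-seq libraries of 116 common bottlenose dolphins, 1 library per animal. Per the labels' protocols, RNA was extracted with a column kit for lipid-rich tissue with DNase digestion, and libraries were made with a directional kit for Illumina sequencing. Per the submitters' processing notes, the tools named are Trimmomatic, FastQC, Bowtie2 2.2.4 and RSEM, with no role or order given; the genome build and annotation version are not given in the sources used here.

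For each animal the authors deposited a table of 21265 genes with a length, an expected count, a TPM and an FPKM value per gene, per the file headers. Expected counts are estimates that share reads between transcripts, and 2.47% of the deposited expected counts were not whole. TPM and FPKM were computed by the authors and scale the counts by transcript length and library; the TPM values were read to learn what the deposited files hold and were not tested. The series table of the authors holds the FPKM values of the same 116 libraries and was identical to them, with a largest difference of 0. The effective length equals the length in every row, and 18698 of the 21265 lengths are multiples of 3. A total of 3598 genes had no count in any animal. The counts of 599 genes were identical to those of another gene in all libraries, 321 of them under 200 bases, so reads of near-identical copies cannot be told apart for these. No pair of libraries held identical counts, and Spearman correlations between libraries ran from 0.923 to 0.983.

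Site, sex and date of collection were taken from the labels, and the seasons were May, June to September, and November to February. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): trimmed mean of M-values (TMM) normalization, the default expression filter, and the quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. Gulf and Atlantic males were compared with season as a term. The winter comparison at CAWS had no covariate and that at Mississippi Sound had sex; their difference was tested as an interaction of site and season with sex as a term. Gulf sites, periods and sexes were tested in 1 fit of all 65 Gulf libraries with sex, period and site as terms. The Atlantic sites, and the years at CAWS, were compared without covariates. Standard errors of log2 fold changes were obtained from the F statistic, and CPM values in the text are TMM-scaled. The Gulf site and period fold changes are adjusted values from the fit.

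The alternatives were DESeq2 1.42.0 size factors (RLE) in edgeR, no filter, a filter on an upper-median CPM of at least 1 over the fitted libraries, the DESeq2 Wald test, limma 3.58.1 with a trend on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM values, library size as a term, and other covariates and sample subsets. These, the tests and the comparisons were fixed before the data were examined. Library class (at least 1000 CPM on transcripts of under 100 bases, or less), the subsets by class, month of collection as a term, leaving out transcripts of under 200 bases, and leaving out single libraries that stood apart were chosen after seeing the data.

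The edgeR test of each comparison was tested on simulated data, in which 200 genes were changed by 1.5, 2 or 4-fold. DESeq2 and the FPKM test were simulated for winter at Mississippi Sound alone. The simulated counts varied independently between genes and held no effects of period, sex, date or library class. The shares below may therefore be more favourable than those in the real libraries. For the regional comparison, simulated over 12327 genes, 95.5% of the genes changed by 2-fold were recovered, and 83.6% of those changed by 1.5-fold. For the winter comparison at Mississippi Sound, over 11340 genes, the shares were 74.6% and 14.9%, and 97.0% for 4-fold. The share of calls that fell on unchanged genes there was 3.13% with edgeR, 9.87% with DESeq2 and 4.80% with the FPKM test, and with edgeR it was highest between Barataria Bay and Chandeleur Sound, at 8.07% over 12596 genes. Intervals between libraries rest on animals, and low counts limit what can be seen: the shallowest library held 3028355 counts.

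The rule for named genes, fixed beforehand, took the genes with the largest positive and negative log2 fold changes past the threshold with a mean log2 CPM of at least 1 and a gene symbol, and members of fixed gene lists. The files pair no identifier with a name, and 0 identifiers matched the RefSeq gene table of assembly mTurTru1.mat.Y used for names. So the symbol part could not be applied, and the gene lists and their set tests could not be run. At most 2 genes that rose and 2 that fell are given per comparison by identifier. That is fewer than the fixed rule asked for and departs from it.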

Results

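Skin RNA was sequenced from 116 common bottlenose dolphins, 65 from the northern Gulf of Mexico and 51 from the southeastern Atlantic coast of the United States. The Gulf animals came from Barataria Bay (22), Mississippi Sound (29) and Chandeleur Sound (14) and were sampled between May 2010 and February 2012. The Atlantic animals came from 2 South Carolina sites, the basin of the Cooper, Ashley, Wando and Stono rivers (CAWS, 38) and that of the Ashepoo, Combahee and Edisto rivers (labelled here ACE, 13), and were sampled between May 2012 and August 2014. All 51 Atlantic animals were male, and the Gulf animals were 30 females and 35 males. Each library is one animal, so the spread between libraries includes the spread between animals. Total expected counts ran from 3028355 to 20089239 per library, with a median of 8137357. The median total was 6652767 in the Gulf and 9166092 in the Atlantic. The genes are known here by their identifiers alone, because none of the identifiers could be paired with a gene name.

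The first principal component of log2 CPM (counts scaled to a common library total) held 32.3% of the variance over 11916 genes, and season of collection accounted for 93.5% of its variance between libraries. The second component held 16.8% of the variance, and region accounted for 87.8% of it. Libraries of November to February lay apart from those of May to September on the first component, and the Gulf and Atlantic libraries lay apart on the second.

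**Figure D1:**
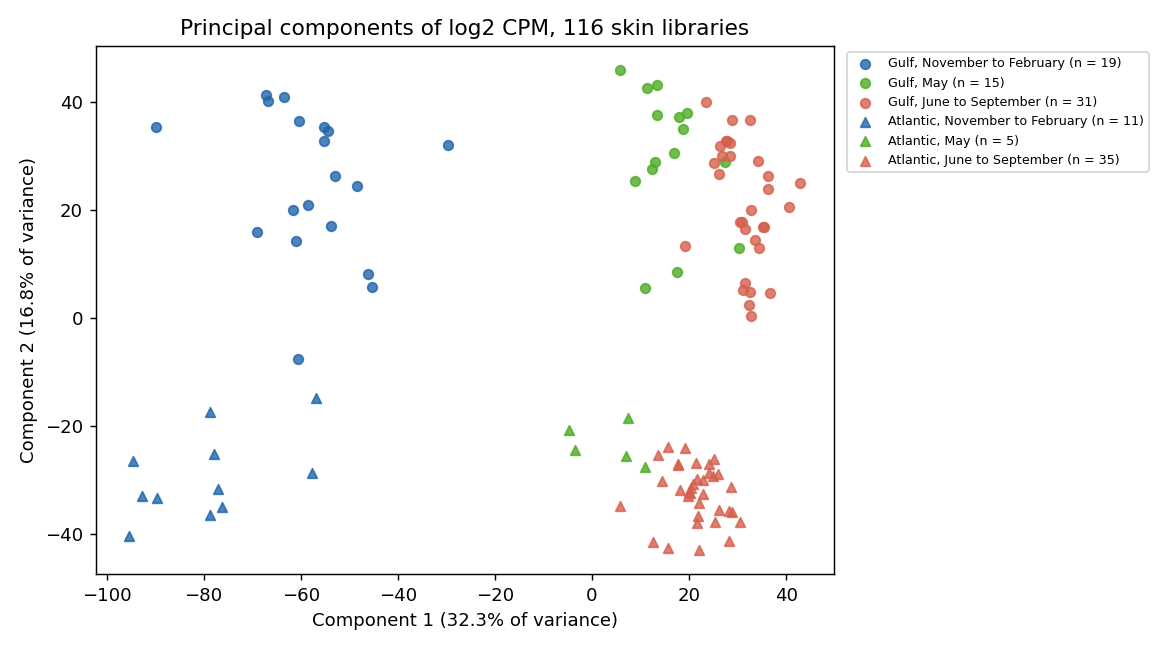
Principal components of log2 CPM for the 116 libraries, with each point one animal, the horizontal axis component 1 (32.3% of variance) and the vertical axis component 2 (16.8% of variance); circles are Gulf and triangles Atlantic animals, and colours give the season. The libraries of November to February lie to the left of all others, and the Gulf libraries lie above the Atlantic libraries.

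One feature of the libraries cut across the design and is given here because it bears on the comparisons that involve the Gulf. Of the 65 Gulf libraries, 42 carried between 1245 and 4496 CPM on transcripts of under 100 bases, and the other 23 carried between 231 and 494 CPM. The 51 Atlantic libraries carried between 83.8 and 556 CPM. Both kinds of Gulf library occurred at all 3 sites and in both sexes, and those with many such reads came from 23 of 30 females and 19 of 35 males. The Gulf libraries with many such reads were also shallower, with a median total of 5714422 against 9241871.

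**Figure D2:**
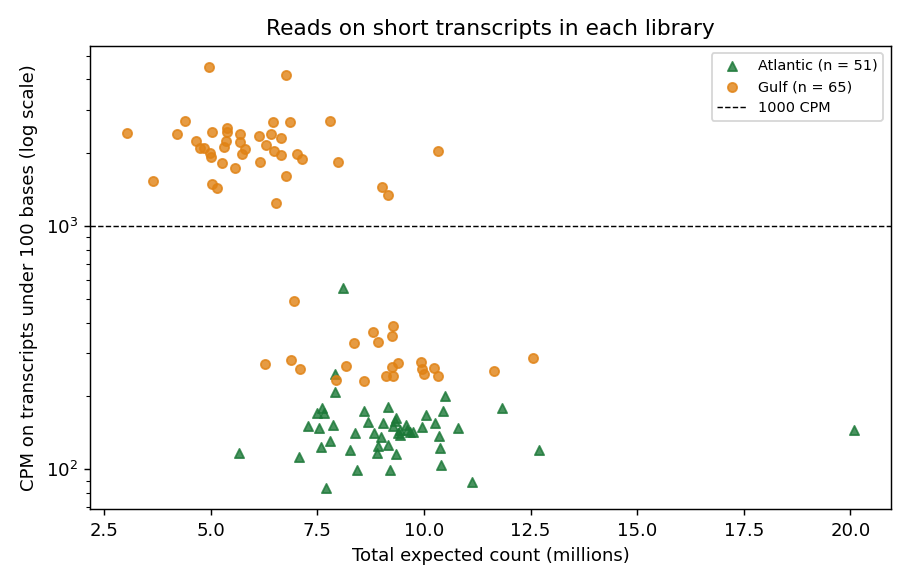
CPM on transcripts of under 100 bases (vertical axis, log scale) against the total expected count (horizontal axis, in the unit printed there), 1 point per library, with triangles for the 51 Atlantic and circles for the 65 Gulf libraries; the dashed line is 1000 CPM. The 42 Gulf libraries above the line carry at least 1245 CPM, and the other 23 lie closer to the Atlantic libraries.

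The winter comparison at CAWS asked how skin expression differed between November 2013 to February 2014 (11 males) and July to August 2014 (12 males). ENSTTRG00000014060 rose from 0.0193 ± 0.0452 CPM in summer (SD, n = 12) to 13.6 ± 5.58 CPM in winter (SD, n = 11); 10 of the 12 summer libraries had no count for it, while every winter library had at least 43. ENSTTRG00000001698 rose from 0.0221 ± 0.0764 to 4.49 ± 1.14 CPM in the same libraries. ENSTTRG00000009840 fell from 24.1 ± 7.64 to 0.465 ± 0.497 CPM, a log2 fold change of -5.62 ± 0.31 (SE), and ENSTTRG00000004378 fell from 6.70 ± 2.92 to 0.110 ± 0.138 CPM, a log2 fold change of -5.82 ± 0.41 (SE). In each of these genes the winter and summer ranges did not overlap. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8430 of the 11422 genes tested passed an adjusted p of 0.05, with 4170 higher and 4260 lower in winter. Of these, 1199 rose and 1713 fell by at least 2-fold.

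The winter comparison at Mississippi Sound set 9 animals of December 2011 against 10 of August 2011, with sex as a term. ENSTTRG00000014060 rose here as well, from 0.0400 ± 0.0880 CPM in summer (SD, n = 10) to 11.1 ± 3.89 CPM in winter (SD, n = 9), and 8 of the 10 summer libraries had no count for it. ENSTTRG00000014282 rose from 0.0929 ± 0.127 to 7.92 ± 3.31 CPM. ENSTTRG00000016268 fell from 76.5 ± 36.5 to 3.26 ± 1.52 CPM, with a log2 fold change of -4.62 ± 0.26 (SE), and ENSTTRG00000010073 fell from 5.27 ± 2.93 to 0.215 ± 0.262 CPM, with a log2 fold change of -4.54 ± 0.49 (SE). The test called 6496 of 11487 genes, 3161 higher and 3335 lower in winter, and 2643 of them changed by at least 2-fold. With the 11 males alone the count was 4201. The share of calls higher in winter was 48.7%, and it was 62.0% on log2(FPKM + 1) values, where the median log2 fold change of all genes was 0.16. With library class (many or few short-transcript reads) as a term, 93.9% of the called genes were called again in the same direction.

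The winter changes at CAWS and Mississippi Sound, which share no libraries, overlapped. Among the 11187 genes tested at both sites, 2667 were called higher in winter at both, where independent lists of these lengths would share 1143. Another 2812 were called lower at both, where independent lists would share 1210. Only 70 genes were called in opposite directions. Of the genes called at CAWS, 90.7% had the same sign at Mississippi Sound. The log2 fold changes of the sites had a Pearson correlation of 0.87 across genes, which are not independent replicates.

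A winter score was computed for each library as the mean log2 CPM of the genes that rose at least 2-fold in winter at CAWS minus that of the genes that fell at least 2-fold. In Gulf animals, which took no part in choosing these genes, the score was 1.72 ± 0.17 (SD, n = 9) at Mississippi Sound in December 2011 and -0.79 ± 0.10 (SD, n = 10) in August 2011. At Barataria Bay it was 1.32 ± 0.26 (SD, n = 8) in February 2012 and -0.88 ± 0.05 (SD, n = 4) in August 2010, a difference with an exact two-sided permutation p of 0.0020, the smallest that 495 splits can give. The May 2010 libraries of Barataria Bay stood at -0.42 ± 0.09 (SD, n = 9), between the winter and August values of that site. Those of Mississippi Sound stood at -0.30 ± 0.09 (SD, n = 4). The 2 of Chandeleur Sound stood at -0.79 and -0.73, within or close to the range of -0.92 to -0.75 of its 5 libraries of August to September 2010. These 2 were from days 27 and 28 of May, and the May libraries of the other Gulf sites from days 8 to 17. Site was therefore not separated from date in May. At CAWS, where the genes were chosen, the score was 1.64 ± 0.03 (SD, n = 2) in November 2013, 2.30 ± 0.02 (SD, n = 4) in December 2013 and 2.81 ± 0.23 (SD, n = 5) in February 2014. With genes chosen at Mississippi Sound instead, the same CAWS months stood at 1.26 ± 0.04, 1.90 ± 0.09 and 2.12 ± 0.12.

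**Figure D3:**
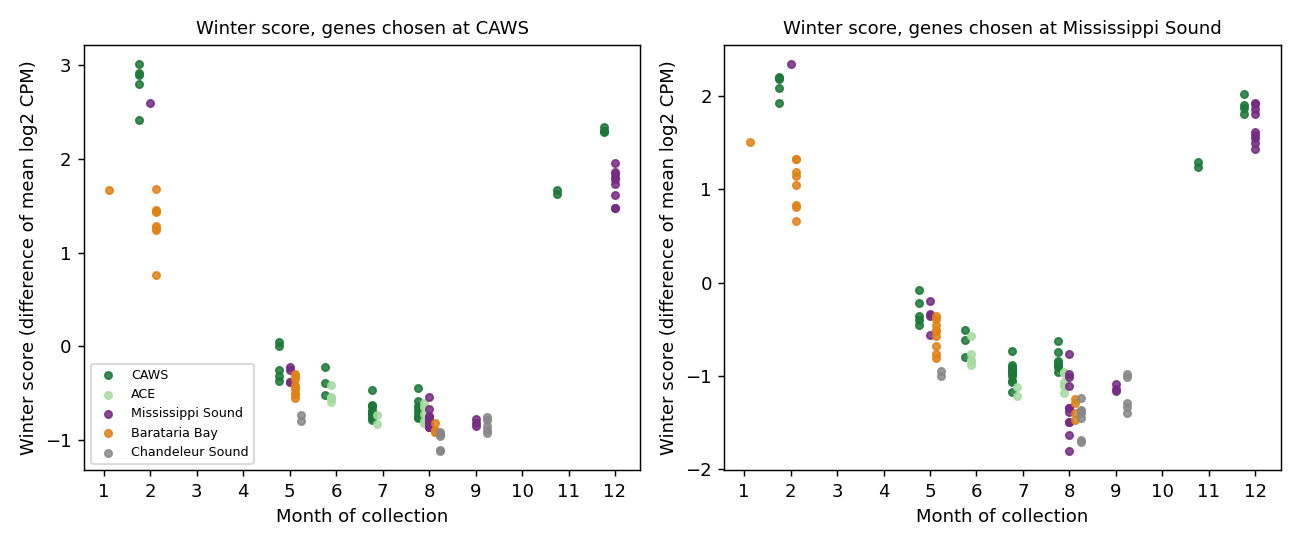
Winter score of each library (vertical axis, difference of mean log2 CPM) against the month of collection (horizontal axis, 1 to 12), with genes chosen at CAWS on the left and at Mississippi Sound on the right; each point is one animal and colours give the site. Libraries of months 11, 12, 1 and 2 lie above those of months 5 to 9 in both panels.

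The difference of the winter effect between CAWS and Mississippi Sound was tested as an interaction over the 42 libraries. ENSTTRG00000013195 had a log2 fold change of 1.96 ± 0.64 (SE) at CAWS and of -1.40 ± 0.48 at Mississippi Sound, and ENSTTRG00000009395 of 4.47 ± 0.81 and 1.38 ± 0.37. In the other direction, ENSTTRG00000003497 had one of -1.40 ± 0.33 at CAWS and of 1.59 ± 0.63 at Mississippi Sound, and ENSTTRG00000010943 of -3.52 ± 0.34 and -0.64 ± 0.41. The interaction passed the threshold in 1523 of 12325 genes, 836 with a more positive and 687 with a more negative change at CAWS. Of the 1467 called genes tested at both sites, 885 had log2 fold changes of the same sign at both and 582 of opposite sign, 70 of which were called at both. The sites also differed in year, month and library class, and the count was 969 with library class as a term. The share of calls more positive at CAWS was 54.9% in the counts and 10.2% on log2(FPKM + 1), where the median log2 difference of all genes was -0.20.

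Gulf and Atlantic males were compared with season as a term (35 against 51). ENSTTRG00000002828 was at 31.5 ± 34.2 CPM in Gulf males (SD, n = 35) and at 1049 ± 375 CPM in Atlantic males (SD, n = 51), a log2 fold change of -5.28 ± 0.21 (SE). ENSTTRG00000014641 was at 87.8 ± 53.8 CPM in the Gulf and 1097 ± 246 CPM in the Atlantic, a log2 fold change of -3.70 ± 0.15 (SE). For both of these genes the highest Gulf male lay below the lowest Atlantic male. The largest increases were in very short transcripts. ENSTTRG00000021768, of 120 bases, was at 45.0 ± 69.0 CPM in the Gulf and 0.112 ± 0.247 CPM in the Atlantic, and ENSTTRG00000023328, of 118 bases, at 8.28 ± 8.50 and 0.0158 ± 0.0684 CPM. They had no count in 40 and 47 of the 51 Atlantic libraries.

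The test called 7445 of 12519 genes between the regions, 4076 higher and 3369 lower in the Gulf, and most differences were small: the median absolute log2 fold change of the called genes was 0.37, and 638 genes passed with at least a 2-fold difference. The share of calls higher in the Gulf was 54.7% in the counts. It was 48.0% on log2(FPKM + 1) and 46.7% on log2(FPKM + 0.1). Genes with transcripts of under 200 bases stood apart, with a median log2 fold change of 1.73 over 247 genes (0.85 with only the Gulf males with few short-transcript reads and 2.22 with only those with many), against 0.03 over 2825 genes of at least 500 and under 1000 bases. Within the Gulf libraries with few short-transcript reads (16 males) the count against the Atlantic males was 7107, and within those with many (19 males) it was 6319. Among males of November to February alone it was 3031. No calendar year held June to September males of both regions, so region could not be separated from year of collection.

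The 3 Gulf sites were compared within shared sampling periods over all 65 Gulf libraries. The 8 Barataria Bay libraries of February 2012 and the 9 Mississippi Sound libraries of December 2011 shared their period with no other site. They gave no direct comparison of sites. Barataria Bay and Chandeleur Sound shared only the periods May 2010 (9 and 2 libraries) and August to September 2010 (4 and 5). Their dates did not overlap within these periods. The 4 Barataria Bay libraries were from August and the 5 of Chandeleur Sound from September. In May, Chandeleur Sound was sampled on days 27 and 28, and the other Gulf sites on days 8 to 17. Between these 2 sites, site was therefore not separated from date. Between Chandeleur Sound and Mississippi Sound, ENSTTRG00000008963 was higher by a log2 fold change of 0.61 ± 0.10 (SE) and ENSTTRG00000014226 by 0.62 ± 0.13, while ENSTTRG00000015844 was lower by -0.95 ± 0.19 and ENSTTRG00000017318 by -0.49 ± 0.10. The test called 8 of 12834 genes, 4 in each direction. In fits with fewer libraries it called 2 with only the 2 sites and 0 within each library class, and DESeq2 called 39. On log2(FPKM + 1) the share of calls higher at Chandeleur Sound was 95.7% of 23, and on log2(FPKM + 0.1) it was 83.3% of 6. Between Barataria Bay and Mississippi Sound it called 1 gene, ENSTTRG00000014485, named outside the rule for named genes after its values were seen, with a log2 fold change of -6.53 ± 1.18 (SE). That gene had a count in 3 of the 22 Barataria Bay and 5 of the 29 Mississippi Sound libraries, with at most 26 counts. Between Barataria Bay and Chandeleur Sound edgeR called 0 genes. At an unadjusted p of 0.05, 801 genes passed in this comparison, 1302 between Chandeleur Sound and Mississippi Sound and 629 between Barataria Bay and Mississippi Sound, where 642 are expected by chance in each. DESeq2 called 3 genes between Barataria Bay and Chandeleur Sound. In simulated data for this last pair of sites, without effects of period, sex or library class, 80.6% of genes changed by 2-fold were recovered. The share in the real libraries may be lower.

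**Figure D4:**
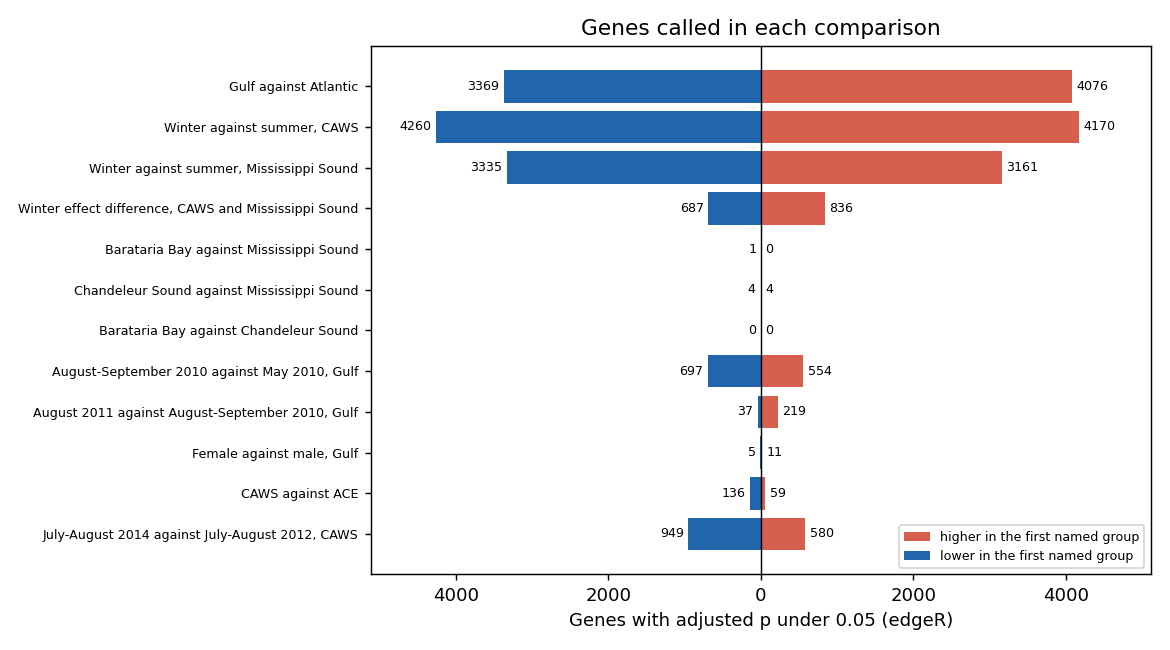
Genes with an adjusted p under 0.05 by edgeR in each comparison, with the number of genes on the horizontal axis; red bars to the right count genes higher and blue bars to the left genes lower in the first named group. The winter comparisons call 8430 and 6496 genes and the regional comparison 7445, and the Gulf site comparisons at most 8.

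Between May and August to September 2010 in the Gulf, ENSTTRG00000014060 fell, with a log2 fold change of -3.34 ± 0.49 (SE), and ENSTTRG00000002187 fell with one of -3.27 ± 0.49. The first was low in both periods, at 0.616 ± 0.495 CPM in May and 0.0413 ± 0.0882 CPM later (SD, n = 15 and 14). The second was at 2.30 ± 2.06 and 0.212 ± 0.290 CPM. Their mean log2 CPM for naming was taken over all 65 Gulf libraries, with those of winter among them. ENSTTRG00000012281 rose by 2.73 ± 0.42, from 0.580 ± 0.541 to 3.86 ± 1.96 CPM. ENSTTRG00000011356 rose by 4.11 ± 1.13, from 0.767 ± 2.55 to 4.30 ± 10.4 CPM. It varied widely between libraries, from 0 to 9.95 CPM in May and from 0 to 31.5 CPM in August to September. The comparison of 14 late-summer with 15 May libraries called 1251 genes, 554 higher and 697 lower in August to September. With library class as a term the count was 1376. Within the libraries with many short-transcript reads it was 343, and within those with few it was 5, in fits with fewer libraries.

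Between August to September 2010 (14 libraries) and August 2011 (17 libraries), ENSTTRG00000013080 rose by a log2 fold change of 1.35 ± 0.30 (SE) and ENSTTRG00000005428 by 1.27 ± 0.20. ENSTTRG00000014556 fell, with a log2 fold change of -1.06 ± 0.27, and ENSTTRG00000009025 fell with one of -1.05 ± 0.29. No Barataria Bay library was from August 2011, so its 4 libraries of 2010 added little to this contrast with site as a term. All 5 Chandeleur Sound and 3 of 5 Mississippi Sound libraries of 2010 were from September. Year was therefore not separated from month. The test called 256 genes, 219 higher and 37 lower in 2011, but 7 with library size as a term. With library class as a term it called 357, among them all 256, and within the libraries with many and with few short-transcript reads, in fits with fewer libraries, 0 and 1. The share of calls higher in 2011 was 85.5% in the counts, 86.5% with RLE size factors and 85.5% with DESeq2. It was 5.22% on log2(FPKM + 1), which carries no TMM scaling. There 766 genes were called, and the median log2 fold change of all genes was -0.15. Of the 256 genes, 76 were called again there in the same direction. So the balance of directions among the calls differed between the counts and the FPKM values. How many of the 256 genes reversed was not counted. The FPKM fit also used another test, so scaling was not isolated as the cause.

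Gulf females (30) and males (35) differed in few genes. ENSTTRG00000000322 was lower in females, at 2.41 ± 1.40 CPM against 10.5 ± 4.21 CPM in males (SD, n = 30 and 35), with a log2 fold change of -2.15 ± 0.16 (SE). ENSTTRG00000003230, of 135 bases, was also lower in females, at 7.55 ± 3.21 against 19.7 ± 11.6 CPM. ENSTTRG00000013331 was higher in females, at 79.6 ± 20.4 against 48.1 ± 9.46 CPM, and ENSTTRG00000006005 at 54.1 ± 18.1 against 33.2 ± 9.81 CPM. The test called 16 genes, 11 higher and 5 lower in females, with 3 called within the 23 libraries with few short-transcript reads and 11 within the 42 with many.

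The Atlantic sites were compared in males of June to August 2012, 10 from CAWS and 13 from ACE. ENSTTRG00000009002 was lower at CAWS, at 12.7 ± 3.36 CPM (SD, n = 10) against 30.6 ± 9.68 CPM (SD, n = 13), and ENSTTRG00000012076 at 1.27 ± 0.56 against 2.76 ± 1.27 CPM. ENSTTRG00000014238 was higher at CAWS, at 3.61 ± 2.86 against 0.993 ± 0.601 CPM, and ENSTTRG00000003384 at 4.14 ± 1.95 against 1.74 ± 1.21 CPM. The test called 195 of 11489 genes, 59 higher and 136 lower at CAWS, and 6 of these differed by at least 2-fold. DESeq2 called 424 genes. The sites differed in month, with 3 June, 6 July and 1 August libraries at CAWS and 5, 2 and 6 at ACE, and with month as a term, chosen after seeing the data, edgeR called 6 genes, 5 of them among the 195. ENSTTRG00000009002 stayed called in that fit, and the other 3 named genes kept their sign and lost the call.

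The years 2014 (12 males) and 2012 (7 males) were compared at CAWS in July to August. ENSTTRG00000000893 was at 19.4 ± 13.8 CPM in 2014 (SD, n = 12) against 64.5 ± 39.6 CPM in 2012 (SD, n = 7), and ENSTTRG00000000240 at 1.15 ± 0.43 against 4.35 ± 3.63 CPM. ENSTTRG00000016837 was higher in 2014, at 4.25 ± 3.33 against 0.989 ± 1.16 CPM, and ENSTTRG00000010992 at 3.47 ± 2.55 against 0.967 ± 0.774 CPM. The test called 1529 of 11726 genes, 580 higher and 949 lower in 2014, and 77 of them differed by at least 2-fold. The years differed in month, with 6 July and 1 August libraries in 2012 and 6 of each in 2014, and with month as a term 728 genes were called, 693 of them among the 1529. The share of calls higher in 2014 was 37.9% in the counts and 69.2% on log2(FPKM + 1).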

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

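Library class was defined after seeing the data, so the tests that use it were chosen then, as were those of year and trips, of season at Barataria Bay, of length among longer genes, of the split in short-transcript reads and of leaving out single libraries; the bounds for the tests of depth, of library class and of length over all genes were written before the values they test were seen.

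The winter effect differed between CAWS and Mississippi Sound in 1523 genes by the interaction test. In ENSTTRG00000013195 and ENSTTRG00000009395 the effect at CAWS exceeded that at Mississippi Sound by 3.35 and 3.12 on the log2 scale, and in ENSTTRG00000003497 and ENSTTRG00000010943 the difference was -3.01 and -2.88. No explanation was weighed for this difference, and year, month and library class differed between the sites. Exchanging site among the males within season, 1 of 100 splits (the real one) reached 1523 genes, and the highest other gave 118. These exchanges also mixed the difference between the sites that holds in both seasons, and the sites lie in different regions. So the splits cannot decide whether the difference of the winter effect itself arose by chance.

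Single libraries stood far from their group in 6 of 32 looks, where chance gives about 1 in 20. The gap to the nearest library, as a share of the group's range, was 0.606 for the library total of CAWS in June to August 2012 and 0.847 in July to August 2012, from the same library of 20089239 counts. It was 0.506 for short-transcript CPM in CAWS in June to August 2012 and 0.489 for log2 CPM of ENSTTRG00000003384 in that group. At Mississippi Sound in August 2011 it was 0.564 for short-transcript CPM and 0.616 for the winter score from CAWS genes. Without the deepest CAWS library of 2012 (replicate 11), 156 genes were called between CAWS and ACE and 1190 between the years at CAWS. Without the Mississippi Sound library of the highest August 2011 score (replicate 15), 6533 were called for winter there and 1349 for the difference of the winter effect.

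The first pattern weighed is the 7445 genes between Gulf and Atlantic males. Depth and library class as the whole cause are argued against: with library size as a term, 86.7% of the called genes were called again in the same direction, and with only the Gulf males whose libraries carry few short-transcript reads, 81.0% were. Transcript length stays partly open over all tested genes, since a curve of length explained 26.6% of the variance of log2 fold change, between the bounds set beforehand, but among genes of at least 500 bases it explained 0.474%. Year of collection cannot be told apart from region, because 0 calendar years held June to September males of both, and library preparation by year is confounded in the same way. A difference between the animals of the 2 coasts stays open as well. Of 100 splits within season only the real one gave as many genes (highest other 113), which argues against chance.

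The second pattern is the winter change. If trip batches moved genes independently at CAWS and Mississippi Sound, the signs of change would match only by chance. But 90.7% of the genes called at CAWS had the same sign at Mississippi Sound, which argues against batches that act independently. Batches that move the same genes at both sites were not tested. Library class is argued against by the 93.9% of Mississippi Sound calls that were called again with class as a term. At Barataria Bay, in other animals and years, the genes called at CAWS shifted between August 2010 and February 2012 by a median of 67.8% of their CAWS change, which is consistent with season of collection as a hypothesis. What in the seasons goes with it was not tested. Of 100 splits the real one alone gave 8430 genes at CAWS (highest other 3378) and 6496 at Mississippi Sound (highest other 2880). That argues against chance.

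The third pattern is the split of the Gulf libraries in short-transcript reads. It occurred at all 3 sites and in 5 of 6 periods, which argues against either as the whole cause; Fisher's exact test gave p = 0.449 for site and p = 0.689 for period. The libraries with many such reads had totals 1.53-fold lower, with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give, so a sequencing or library batch is a candidate explanation. The labels give no such batch, and lower totals alone do not single one out. Fisher's exact test of the split against the prefix of the sample titles gave p = 0.714. What the prefix stands for is not given. Many such reads were found in 23 of 30 females and 19 of 35 males (Fisher's exact two-sided p = 0.0730), so sex as a part of the pattern stays open, and no other biological explanation was tested.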

How the results depend on the processing

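The alternatives by library class, with month as a term and without transcripts of under 200 bases or without single libraries were chosen after seeing the data, as were those for the genes shared by both winter comparisons. No paired analysis was possible because replicate numbers follow accession order and pair no animals. The alternatives for the fixed gene lists, a set test with an estimated correlation and a rotation test, were not run, since no identifier could be matched to a gene name in the sources used here. The count of genes stayed within 1.5 times the main count in 117 alternative fits over all comparisons and moved further in 39. No named gene changed sign in 466 fits of a named gene under an alternative, and 407 of them kept the call in the same direction. The named genes were picked for large changes in the same libraries, so a kept sign was likely beforehand. Fits in which a gene was filtered out were not counted. The 5479 genes shared by both winter comparisons stayed within 1.5 times under each alternative run at both sites. Limits of depth apply most to the Gulf libraries, with a median total of 6652767.

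The cause of the following changes was not tested, except that a subset has fewer libraries by construction. Between Gulf and Atlantic, November to February males gave 3031 genes in place of 7445. For winter at Mississippi Sound, males only gave 4201 in place of 6496. For the difference of the winter effect, library class as a term gave 969 in place of 1523. Between Barataria Bay and Mississippi Sound (1 gene), season in place of period gave 536, no covariates 39 and no filter 2, while a filter on an upper-median CPM of 1, DESeq2, both FPKM scales, only the 2 sites, and each library class alone gave 0. Between Chandeleur Sound and Mississippi Sound (8 genes), no covariates gave 2291, DESeq2 39, log2(FPKM + 1) 23, no filter 4, only the 2 sites 2 and each library class alone 0. Between Barataria Bay and Chandeleur Sound (0 genes), no covariates gave 2315, DESeq2 3, no filter 1, only the 2 sites 2 and the libraries with few short-transcript reads 2. The fits with no covariates mix site with season, since the sites were sampled in different months. For August to September against May 2010 (1251 genes), the libraries with few short-transcript reads gave 5 and those with many 343. For August 2011 against August to September 2010 (256 genes), DESeq2 gave 470, log2(FPKM + 1) 766, log2(FPKM + 0.1) 804, library size as a term 7, only the 2 periods 72, and the libraries with few and with many short-transcript reads 1 and 0. For the sexes (16 genes), no covariates gave 10 and the libraries with few short-transcript reads 3. Between CAWS and ACE (195 genes), DESeq2 gave 424 and month as a term 6, and between the years at CAWS (1529 genes) month as a term gave 728. FPKM values carry no TMM scaling, and on log2(FPKM + 0.1) the share of calls higher was 62.2% for winter at Mississippi Sound, 9.24% for the difference of the winter effect, 5.47% for August 2011 and 70.2% for 2014 at CAWS. Leaving out single libraries gave 6533 genes (without Mississippi Sound replicate 15) for winter there and 1349 for the difference, and 156 and 1190 genes (without CAWS replicate 11) for CAWS against ACE and for the years at CAWS.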

Other observations

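Some genes separated the seasons in every library. Of 15812 genes with at least 10 counts in all, 344 had no overlap between the 30 libraries of November to February and the 66 of June to September, over all sites and both sexes, with 177 higher and 167 lower in the cold months; a chance split of these sizes gives practically none. On CPM of library totals, without TMM, the count was 311, with 225 higher and 86 lower. Between the 65 Gulf and 51 Atlantic libraries 25 genes did not overlap, 23 of them higher in the Gulf, and 21 of the 25 were under 200 bases.

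ENSTTRG00000015600, chosen after its values were seen, fell into separate low and high libraries. It was at 2.41 CPM or less in 12 libraries and at 12.0 CPM or more in the other 104. The low libraries were 9 of 38 from CAWS, 2 of 13 from ACE and 1 of 29 from Mississippi Sound, with none among the 22 from Barataria Bay and the 14 from Chandeleur Sound. The share differed between the regions by Fisher's exact test (two-sided p = 0.000473), for a gene picked from many for its shape, so the p is too small.

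The spread within a site and period also varied. The median SD of log2 CPM over genes was 0.23 in the 12 CAWS males of July to August 2014 and 0.45 in the 10 Mississippi Sound animals of August 2011. The Mississippi Sound group held 4 females and 6 males and libraries with many and with few short-transcript reads. The CAWS libraries all carried few such reads. The cause of the difference in spread was not tested.

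Other splits of the same libraries were fitted for the remaining comparisons. Of 100 splits, 1 reached 195 genes between CAWS and ACE (highest other 18) and 1 reached 1529 between the years at CAWS (highest other 413). Likewise 1 reached 1251 between May and August to September 2010 (highest other 645) and 1 reached 16 between the sexes (highest other 7). Each time this was the real split, and 1 is the smallest count that 100 splits can give. That argues against chance in these comparisons but does not exclude it, since many comparisons were split in this way. The splits of the Atlantic sites and of the years did not keep month of collection apart, and with month as a term 6 and 728 genes were called, so these splits do not separate site or year from month. Between August 2011 and August to September 2010, 4 of 100 splits reached 256 genes and the highest other gave 1340; between Chandeleur Sound and Mississippi Sound 2 of 100 reached 8 and the highest other gave 69. Few splits reached these 2 counts, but splits that call several times the real count point to a structure of the samples. With library size as a term the counts were 7 for August 2011 and 7 for Chandeleur Sound, and with library class as a term 357 and 11. For the 1 gene between Barataria Bay and Mississippi Sound 22 of 100 splits gave as many (highest other 2), so chance is not excluded. Between Barataria Bay and Chandeleur Sound any split reaches a count of 0, as all 90 of 90 did (highest other 1), so the splits say nothing about chance there.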
